A study of Mus musculus with 21 samples.

How the data were processed

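Per the submitters' processing notes, reads were trimmed with fastp, aligned to the mouse genome mm10 with HISAT2 and counted with HTSeq, and R 3.2.0 was used. The authors computed FPKM (fragments per kilobase of transcript, scaled to the size of the library) before deposition, and the deposited table holds these FPKM values for 18788 gene symbols in 21 libraries. The annotation, any filter, the strand setting and the other tool versions are not given in the sources used here. Per the labels, RNA was extracted with TRIzol, checked by NanoDrop and Bioanalyzer, and made into libraries with a VAHTS Universal V6 kit. The table has no duplicated symbol (0) and no gene at 0 in every library. Sequencing depth is not in the table. It was estimated from the spacing of the low FPKM values of genes with 1 annotated transcript, using 1075 genes, of which 450 lay in the mode, and at least 22 genes stood behind each relative depth. The estimated depths lay between 33.7 M and 40.5 M reads, where M stands for mega. The estimate assumes the annotated transcript lengths, and only the relative depths are free of that.

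Values were taken as log2(FPKM + 1), and genes with a mean below 0.5 FPKM were left out, which kept 13963 genes. The limma package (3.58.1, R 4.3.3) fitted 1 mean for each of the 6 groups with a trend in the prior variance, leaving 15 residual degrees of freedom. Contrasts were A91-DsEV minus PBS at each time point, their average, the interaction of treatment and time, and successive time points within a treatment. A gene passed at a Benjamini-Hochberg adjusted p below 0.05, adjusted within each comparison. Log2 fold changes are given with the standard error of the fit, and FPKM values as mean and SD of the libraries. Coordinates are those of GENCODE M21 on mm10 and were matched by symbol.

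Of 42 gene lists written before the data were examined, 38 had at least 5 tested members. Of their 639 genes, 625 were in the table, and the others were not analysed here. Values of some named genes are not reported here. Lists were tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, and with fry. All tests were two-sided. The treatment comparisons at each time point and their lists were fixed before the data were examined, while list tests of the time courses, the average and the interaction were added afterwards. Genes were named by a rule fixed beforehand, at a mean of at least 1 FPKM: the 3 higher and 3 lower genes of smallest p where none passed, the 5 largest changes each way between time points, 5 genes for the average and for the interaction, and up to 4 members of a list that passed, of which 2 were used for the treatment comparisons. The rule for list members was extended to the time courses after the values were seen. Alternatives were a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, rescaling to equal FPKM totals, quantile normalization, fits of only the groups compared, the replicate number as a block and each library left out in turn. After the data were examined, array weights and alternatives for muscle and pancreatic transcripts were added. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

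A self-test added known changes to 200 of the 13963 genes in 10 simulations per comparison. The simulated values were drawn independently for each gene, from its mean at each time point and its own spread. At time point 3, 62.0% of 1.5-fold, 89.8% of 2-fold and 98.3% of 4-fold changes passed, at time point 7 61.3%, 90.8% and 99.3%, and at time point 14 62.4%, 91.0% and 98.4%. The direction was right in 100% of them, and 7.2 to 10.1 unchanged genes passed per simulation on average. A shift of 0.5 added to the neuronal list was recovered in 10 of 10 simulations, and 1 of 10 simulations without a shift had a list that passed. These values held no correlation between genes and no library standing apart, so the rates do not carry over to the real libraries. There, other splits of the libraries of time points 3, 7 and 14 passed medians of 14, 14 and 12 lists.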

Results

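RNA sequencing of mouse spinal cord compared animals given A91-DsEV, extracellular vesicles made by dendritic cells, with controls given phosphate-buffered saline (PBS). The labels present the vesicles as a vaccine meant to raise protective immunity in injury of the cord. Samples came from time points 3, 7 and 14, for which the labels give no unit. Each time point had 4 A91-DsEV and 3 PBS libraries, 21 in all. The labels do not say whether replicates were separate animals, so p-values measure only the spread between these samples. The deposited table held FPKM values of 18788 genes. Its low values gave relative depths of 0.907 to 1.092 and an estimated 33.7 M to 40.5 M reads per library. Between 12339 and 12985 genes reached 1 FPKM in a library.

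Some libraries held transcripts of another tissue. In A91-DsEV replicate 2 of time point 7, 20 genes of the exocrine pancreas made up 13.1% of the FPKM total. Ctrb1, a chymotrypsinogen, stood at 9611 FPKM there, Cela2a, a pancreatic elastase, at 9055 FPKM and Pnlip, the pancreatic lipase, at 5066 FPKM. These 20 genes had a median of 0.343 to 0.639 FPKM in 8 other libraries and of at most 0.0165 FPKM in the other 12. The 8 libraries with such traces were 2 of A91-DsEV at time point 3, the other 3 of A91-DsEV at time point 7, 2 of A91-DsEV at time point 14 and 1 of PBS at time point 3. All 4 A91-DsEV libraries and 0 of the 3 PBS libraries of time point 7 therefore carried pancreatic transcripts. Neutrophil genes stood apart in A91-DsEV replicate 4 of time point 3, with a mean log2(FPKM + 1) of 5.46 against 2.07 to 2.49 in the other replicates. These marker lists for other tissues were chosen after the values were seen, apart from the neutrophil list.

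At time point 3, gene lists for dividing cells, resting microglia and cilia lay higher in A91-DsEV than in PBS, and the list for neurons lay lower, in limma's camera test with a preset correlation. None of these calls held with an estimated correlation (adjusted p of at least 0.848), 0 of 38 lists passed fry, and the neuronal call ended without PBS replicate 1 (adjusted p = 0.266). Fcrls, a receptor of microglia, measured 129 ± 14.8 FPKM with A91-DsEV and 78.1 ± 32.4 FPKM with PBS (SD, n = 4 and 3), a log2 fold change of 0.79 ± 0.21 (SE). Rsph1, a radial spoke protein of motile cilia, measured 6.24 ± 0.617 against 3.28 ± 1.66 FPKM. Plin4, which coats lipid droplets, measured 1.38 ± 0.836 against 9.09 ± 5.91 FPKM, a log2 fold change of -1.96 ± 0.36. Pla2g3, a secreted phospholipase, measured 1.39 ± 0.669 against 5.72 ± 3.36 FPKM, a log2 fold change of -1.42 ± 0.24.

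No gene passed the limma test at time point 3. The smallest adjusted p among 13963 genes was 0.0703, for Pla2g3 (chromosome 11, 3488284 to 3499350, mm10). Plin4 (chromosome 17, 56100591 to 56109803) had an adjusted p of 0.0916, and Capsl (chromosome 15, 9436028 to 9466038), which codes for a calcium-binding protein, one of 0.0897 at a log2 fold change of 0.81 ± 0.14. H2bc6, a histone H2B gene, and Isoc2b had log2 fold changes of 0.65 ± 0.13 and 0.51 ± 0.10, and Nudt22 had one of -0.66 ± 0.12. In each of these 6 genes, the 4 A91-DsEV libraries lay beyond every PBS library. At an unadjusted p below 0.05 there were 1370 genes, 901 higher and 469 lower, where 698 were expected by chance. The groups did not overlap in 1092 genes (7.8%), and chance gives 5.7%. Without A91-DsEV replicate 1, Pla2g3 passed (-1.59, adjusted p = 0.0318). Without PBS replicate 2, 103 genes passed, 56 higher and 47 lower. All 103 had the same sign with every library, which tests nothing, since both fits share the remaining libraries. PBS replicate 2 correlated more with A91-DsEV replicates 1, 2 and 3 (Pearson r of 0.996, 0.995 and 0.995) than with PBS replicates 1 and 3 (0.985 and 0.992). Its r with A91-DsEV replicate 4 was 0.990. Among the 103 genes, Fkbp5, a glucocorticoid-induced chaperone chosen after its values were seen, had a log2 fold change of -1.32 without PBS replicate 2 (adjusted p = 0.00117), and Plin4 one of -2.41. Without each of the other 5 libraries 0 genes passed, and without PBS replicate 1 the smallest adjusted p was 0.389, with Plin4 at -1.52 and Fkbp5 at -0.65.

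Of 38 gene lists, 10 passed limma's camera test with a preset correlation at time point 3, 7 higher and 3 lower, and 0 passed with an estimated correlation. All 24 cell cycle genes had positive fold changes, with a median of 0.42 (adjusted p = 1.32e-07, and 0.853 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, measured 28.8 ± 3.89 against 18.7 ± 6.64 FPKM, and Tpx2, a spindle assembly factor, 18.7 ± 0.986 against 12.8 ± 4.81 FPKM. All 11 genes of homeostatic microglia were positive, with a median of 0.40 (adjusted p = 3.48e-06, and 0.848 with an estimated correlation), and 6 passed when adjusted over the list alone. Tmem119, a microglial surface protein, measured 33.1 ± 4.38 against 24.9 ± 4.64 FPKM. Of 8 ependymal and cilia genes, 7 were positive, with a median of 0.51 (adjusted p = 7.5e-05, and 0.848 with an estimated correlation), and 5 passed when adjusted over the list alone.

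Glial and myeloid lists lay higher as well. Oligodendrocyte and myelin genes had a median of 0.26 with 15 of 16 positive (adjusted p = 0.00199), and Opalin, a myelin protein, measured 26.6 ± 3.36 against 15.3 ± 7.24 FPKM. The 10 genes of oligodendrocyte precursors had a median of 0.27 (adjusted p = 0.0281), led by Gpr17 at 18.7 ± 3.11 against 10.4 ± 7.96 FPKM. In each of these lists 1 gene passed when adjusted over the list alone. Macrophage and monocyte genes had a median of 0.33 (adjusted p = 0.00779). Csf1r, the receptor for macrophage growth factor, measured 103 ± 12.3 against 76.7 ± 10.5 FPKM, whereas the scavenger receptor Cd163 measured 2.08 ± 0.402 against 4.97 ± 2.80 FPKM. Lipid-handling phagocyte genes had a median of 0.27 (adjusted p = 0.0281), with the fungal glucan receptor Clec7a at 39.7 ± 5.67 against 23.3 ± 8.37 FPKM. All 19 neuronal genes were negative, with a median of -0.31 (adjusted p = 0.000509), as were all 18 genes of oxidative phosphorylation, with a median of -0.16 (adjusted p = 0.000258). Of 19 genes tied to axon regeneration, 15 were negative, with a median of -0.13 (adjusted p = 0.0137). With an estimated correlation, each of these 7 lists had an adjusted p of 0.853.

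PBS replicate 1 of time point 3 stood apart in several of these lists. Its neuronal score, a mean log2(FPKM + 1), was 5.70 against 4.81 to 5.19 in the other 6 libraries, its cell cycle score 3.03 against 3.62 to 4.04 and its microglial score 4.13 against 4.46 to 4.99. Without it, the axon regeneration, neuronal, oxidative phosphorylation, oligodendrocyte precursor, macrophage and lipid-handling phagocyte lists no longer passed (adjusted p of 0.0531 to 0.544), and the mean log2 fold change shrank from 0.40 to 0.16 for the cell cycle list, from 0.41 to 0.26 for homeostatic microglia and from 0.29 to 0.12 for oligodendrocytes, whose calls held. Leaving out A91-DsEV replicate 1 ended 0 list calls, and leaving out another library ended 1 to 3, among axon regeneration (without A91-DsEV replicate 2 or 4), lipid-handling phagocytes (without A91-DsEV replicate 3 or PBS replicate 3), oligodendrocyte precursors (without A91-DsEV replicate 4 or PBS replicate 3), macrophages (without PBS replicate 2) and oligodendrocytes (without PBS replicate 3), at adjusted p of 0.0506 to 0.206. Among only the libraries without pancreatic traces, A91-DsEV replicates 1 and 2 and PBS replicates 1 and 3, 6 genes passed, all of them lower: Cd163, Crispld2, Fbxw23, Fkbp5, Serpina3m and Slc10a6. This subset again leaves out PBS replicate 2, without which 103 genes passed, among them Cd163, Crispld2, Fbxw23, Fkbp5 and Serpina3m. It also keeps PBS replicate 1, so it is not separate evidence. With the traces as a term of the fit, Fbxw23, Pla2g3 and Serpina3m passed, at log2 fold changes of -1.19, -1.34 and -1.79.

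**Figure D1:**
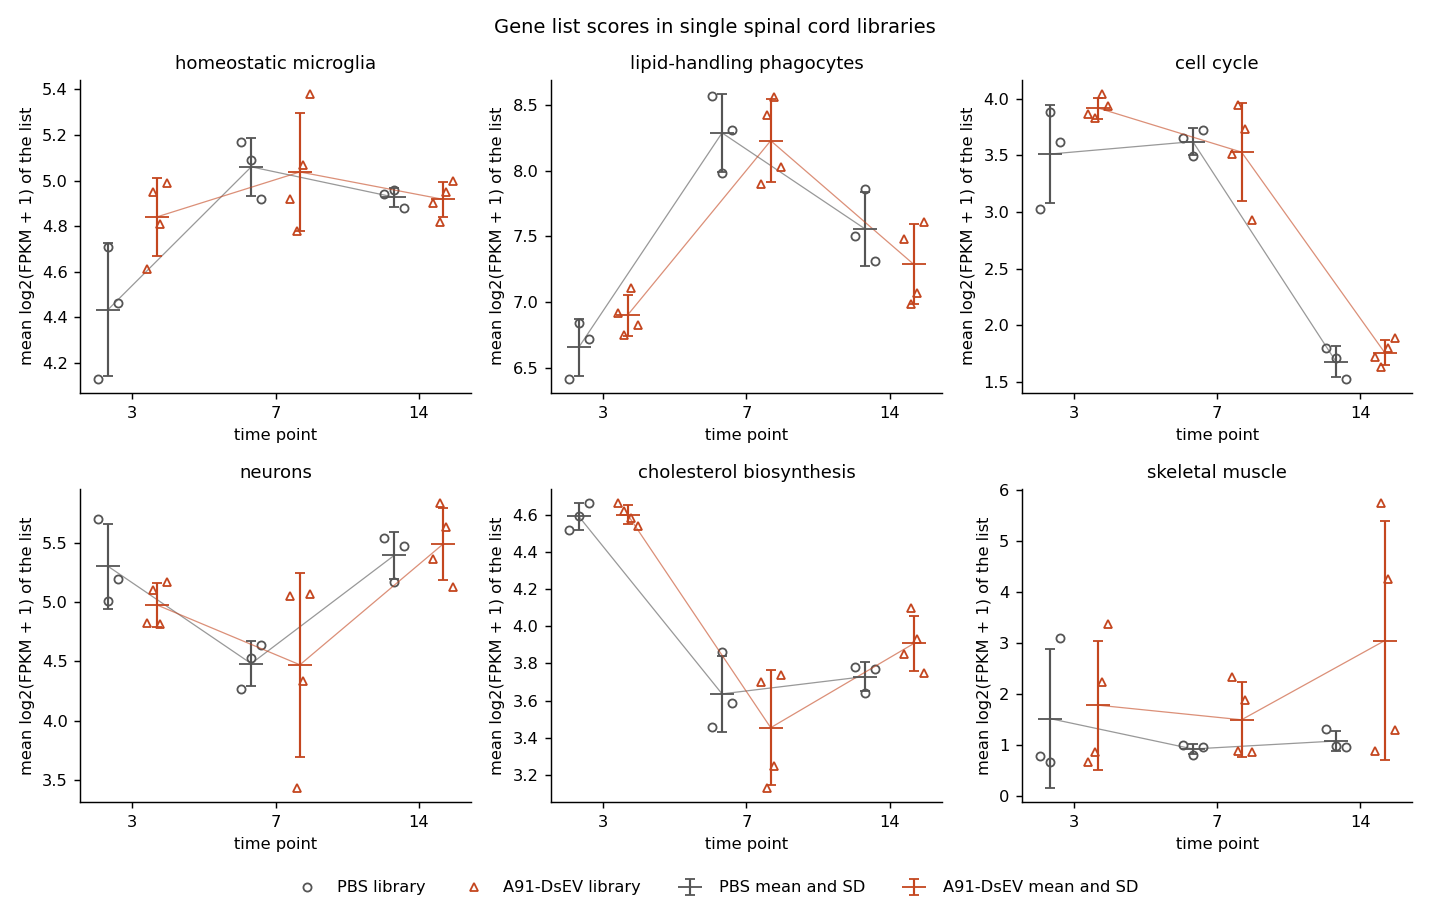
Mean log2(FPKM + 1) of 6 gene lists in each library (y axes) by time point (x axes). Circles are PBS (n = 3) and triangles A91-DsEV (n = 4) libraries, with group means and SD. PBS replicate 1 of time point 3 has the highest neuronal score there, 5.70, and 2 A91-DsEV libraries of time point 14 have skeletal muscle scores of 5.74 and 4.27.

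At time point 7, the red blood cell list lay higher in A91-DsEV in the preset camera test, and genes of the circadian clock had the smallest p-values among lower genes. With an estimated correlation the red blood cell call did not hold (adjusted p = 0.696), and 2 of the 4 A91-DsEV libraries, with scores of 6.73 and 6.71, lay within the PBS range of 6.32 to 6.91. Dbp, a clock-controlled transcription factor (chromosome 7, 45705088 to 45710203), measured 9.68 ± 3.10 FPKM with A91-DsEV and 22.4 ± 2.47 FPKM with PBS (SD, n = 4 and 3), a log2 fold change of -1.17 ± 0.22 (SE). The clock repressors Per3 and Per2 measured 1.61 ± 0.658 against 3.39 ± 0.345 FPKM and 1.44 ± 0.352 against 2.57 ± 0.266 FPKM. The clock activator Npas2 measured 2.19 ± 0.425 against 1.31 ± 0.516 FPKM. Ahsp, which stabilises alpha haemoglobin, measured 79.1 ± 102 against 7.61 ± 2.92 FPKM, and its log2 fold change fell from 2.43 to 1.64 without A91-DsEV replicate 1, at 230 FPKM.

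No gene passed the limma test at time point 7, where Dbp had the smallest adjusted p, 0.761. With the replicate number as a block, Dbp alone passed (-1.35, adjusted p = 0.00794), although the values showed no sign that equal numbers paired the libraries. At an unadjusted p below 0.05 there were 544 genes, 77 higher and 467 lower, fewer than the 698 expected by chance. The median log2 fold change of all genes was -0.048. It was -0.007 after quantile normalization or with values rescaled without exocrine pancreas genes, and -0.009 without A91-DsEV replicate 2, the library rich in pancreatic transcripts. Whether the excess of lower genes depends on this scaling was not tested. The groups did not overlap in 893 genes (6.4%), against 5.7% by chance. All 4 A91-DsEV libraries lay below every PBS library for Dbp, Per2 and Per3.

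In all, 13 lists passed the preset camera test, 5 higher and 8 lower, and 0 passed with an estimated correlation (adjusted p of at least 0.696). All 10 genes of red blood cells were positive, with a median of 0.60 (adjusted p = 5.31e-09, and 0.696 with an estimated correlation), and 4 passed when adjusted over the list alone. The list scored 9.24 and 7.81 in the other A91-DsEV libraries, replicates 1 and 2. Of 14 genes of Schwann cells and peripheral nerve, 13 were negative, with a median of -0.38 (adjusted p = 0.000126). All 18 genes of cholesterol biosynthesis were negative, with a median of -0.19 (adjusted p = 0.00132). All 15 skeletal muscle genes were positive, with a median of 0.49 (adjusted p = 0.00132), but the list scored 2.35 and 1.89 in A91-DsEV replicates 1 and 3 and 0.90 and 0.87 in the other replicates, against 1.0, 0.82 and 0.97 in the PBS replicates. Each of these 3 lists had an adjusted p of 0.696 with an estimated correlation.

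Complement genes had a median of -0.28 (adjusted p = 0.0249), with C3, the central complement protein, at a log2 fold change of -0.56 ± 0.22. Reactive astrocyte genes had a median of -0.24 (adjusted p = 0.0232), with the protease inhibitor Serping1 at 65.6 ± 8.91 against 86.8 ± 0.976 FPKM. Immediate-early genes had a median of -0.25 (adjusted p = 0.00747), endothelial genes one of -0.21 (0.0249), axon regeneration genes one of -0.17 (0.0201) and meningeal genes one of -0.24 (0.0439). Oxidative phosphorylation genes (0.05, adjusted p = 0.00632) and B cell genes (0.10, adjusted p = 0.0439) had positive medians. The interferon-stimulated list passed as higher (adjusted p = 0.0373) with a mean of 0.08 and a median of -0.01, its 21 genes being 10 positive and 11 negative. Rsad2, an antiviral enzyme, had a log2 fold change of 1.03 ± 0.46. With an estimated correlation these lists had adjusted p of 0.696 or, for oxidative phosphorylation and interferon-stimulated genes, 0.804.

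Only the red blood cell and skeletal muscle calls held in all 7 fits without a library of time point 7, with means that shrank from 0.98 to 0.44 and from 0.57 to 0.29 without A91-DsEV replicate 1. Without PBS replicate 2, where Avil, a gene of sensory neurons, stood at 4.49 FPKM against at most 0.322 FPKM elsewhere, 9 list calls ended, the peripheral nerve, cholesterol, astrocyte, axon regeneration, endothelial, meningeal, B cell, interferon and oxidative phosphorylation lists, at adjusted p of 0.0922 to 0.769. PBS replicate 2 stood apart in the peripheral nerve score (3.62 against 3.13 and 3.03 in PBS replicates 1 and 3) but hardly in the meningeal score (4.32 against 4.19 and 4.24). Between 2 and 7 calls ended without another library: 6 without A91-DsEV replicate 1 (0.0949 to 0.471), the cholesterol and B cell calls without replicate 2 (0.137 and 0.244), 3 without replicate 3 (0.201 to 0.228), 7 without replicate 4 (0.137 to 0.568), and 3 each without PBS replicate 1 (0.0547 to 0.313) and replicate 3 (0.0802 to 0.219). With pancreatic traces as a term, 9 of the 13 calls ended (0.0732 to 0.979), and the mean went from -0.40 to 0.04 for the peripheral nerve list and from 0.57 to -0.07 for skeletal muscle. Traces did not vary within either group of time point 7, so the term was set by libraries of time points 3 and 14. These values therefore do not test the difference at time point 7. The trace term itself called 0 genes in limma and had 406 at an unadjusted p below 0.05, fewer than the 698 expected by chance. Within time point 7 these traces and the treatment cannot be told apart.

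**Figure D2:**
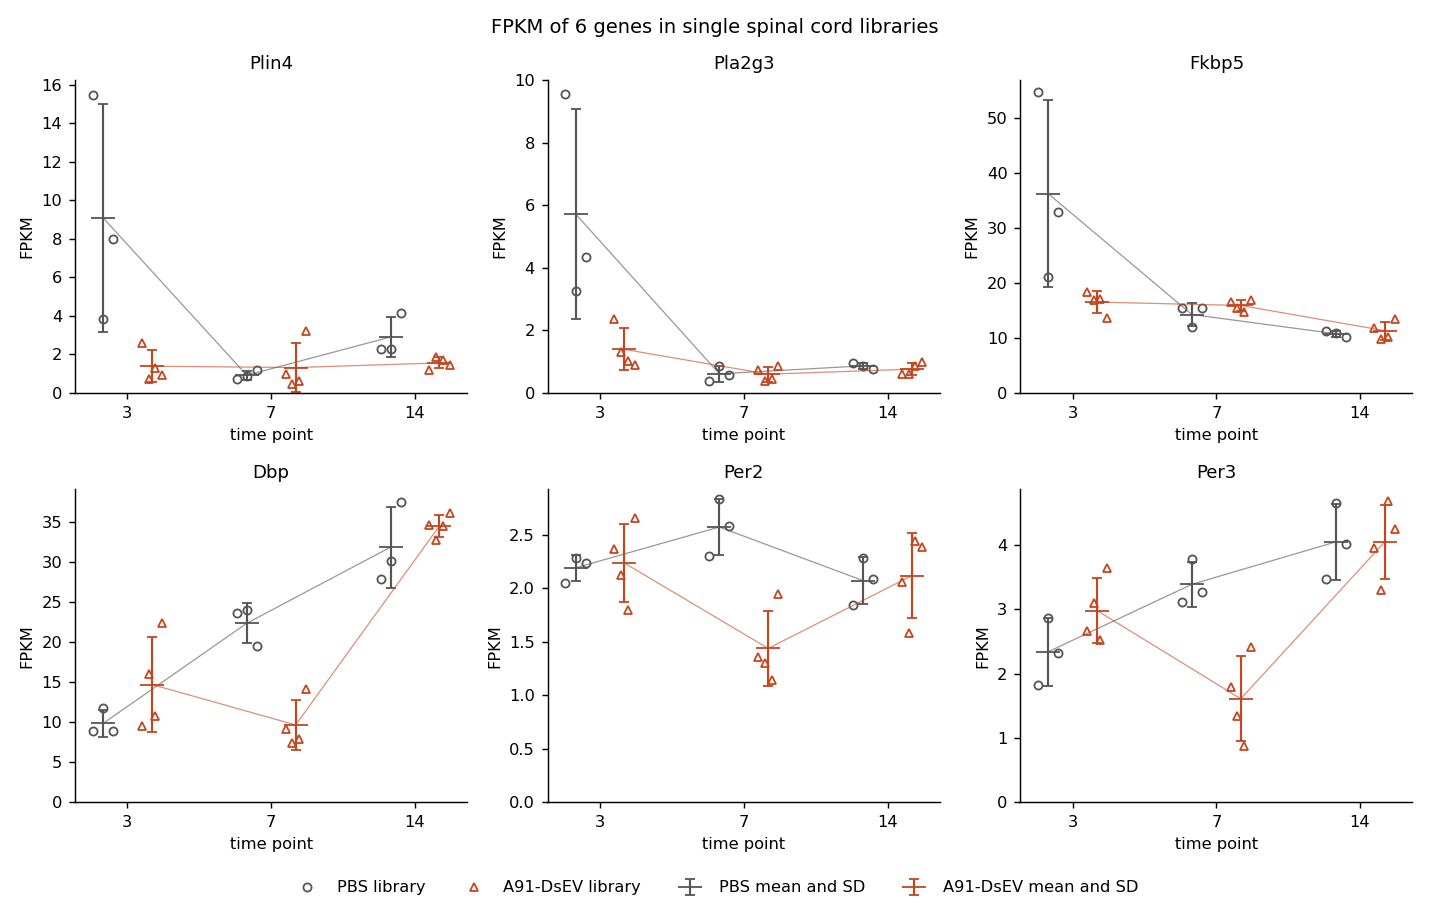
FPKM of Plin4, Pla2g3, Fkbp5, Dbp, Per2 and Per3 in each library (y axes) by time point (x axes). Circles are PBS (n = 3) and triangles A91-DsEV (n = 4) libraries, with group means and SD. Dbp averages, at time point 7, 9.68 FPKM with A91-DsEV and 22.4 FPKM with PBS.

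At time point 14, lists for lipid-handling phagocytes, MHC class I presentation and T cells lay lower in A91-DsEV, and the list for cholesterol biosynthesis lay higher, in the preset camera test. These calls did not hold with an estimated correlation (adjusted p of at least 0.488). They also ended without A91-DsEV replicates 2 and 3, which were rich in muscle transcripts (adjusted p of at least 0.061). The T cell score was 1.92 to 2.01 across the A91-DsEV libraries and 2.12 to 2.46 across the PBS libraries. The end of the T cell call therefore does not show that it rested on the muscle-rich libraries. Apoe, a lipid carrier abundant in phagocytes, measured 7974 ± 1588 FPKM with A91-DsEV and 10290 ± 1548 FPKM with PBS (SD, n = 4 and 3), a log2 fold change of -0.38 ± 0.16 (SE). H2-D1, an MHC class I heavy chain, measured 357 ± 45.0 against 449 ± 54.2 FPKM. The cytokine gene Il1a had a log2 fold change of -0.48 ± 0.16. Ccn3, a matrix-associated signalling protein, measured 16.9 ± 4.38 against 8.50 ± 2.81 FPKM, a log2 fold change of 0.93 ± 0.24.

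No gene passed the limma test at time point 14, where the smallest adjusted p was 1.0. At an unadjusted p below 0.05 there were 275 genes, 103 higher and 172 lower, fewer than the 698 expected by chance, and the groups did not overlap in 497 genes (3.6%, against 5.7% by chance). The smallest p-values among higher genes belonged to Ccn3, Glt8d2 (0.44 ± 0.14) and Coil (0.30 ± 0.10), and among lower genes to the phosphatase subunit Ppp3cc (-0.32 ± 0.08), Mrgpre (-0.36 ± 0.09) and Arrdc1 (-0.31 ± 0.09).

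Here 13 lists passed the preset camera test, 4 higher and 9 lower, and 0 passed with an estimated correlation (adjusted p of at least 0.488). No gene passed when adjusted over its list alone. All 20 genes of lipid-handling phagocytes were negative, with a median of -0.27 (adjusted p = 1.95e-09, and 0.588 with an estimated correlation), among them Gpnmb, a lysosomal glycoprotein, at 493 ± 162 against 741 ± 244 FPKM. Of 12 MHC class I genes, 11 were negative, with a median of -0.13 (adjusted p = 1.58e-05, and 0.488 with an estimated correlation). T cell genes had a median of -0.27 with 6 of 7 negative (adjusted p = 0.00223, and 0.488 with an estimated correlation), and Cd3g, a chain of the T cell receptor complex, measured 1.27 ± 0.216 against 2.63 ± 1.99 FPKM, with its log2 fold change going from -0.55 to -0.13 without PBS replicate 1, at 4.92 FPKM. All 18 cholesterol genes were positive, with a median of 0.17 (adjusted p = 2.75e-07, and 0.588 with an estimated correlation), and Hmgcs1 measured 63.1 ± 5.55 against 51.2 ± 3.60 FPKM.

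Reactive astrocyte genes had a median of -0.16 (adjusted p = 0.00066), with Serpina3n at 325 ± 52.9 against 433 ± 21.6 FPKM. Inflammatory cytokine genes had a median of -0.15 (adjusted p = 0.00556), complement genes one of -0.19 (0.00616), macrophage genes one of -0.09 (0.0423), apoptosis genes one of -0.07 (0.00217) and peripheral nerve genes one of -0.19 (0.00645). Meningeal genes (0.21, adjusted p = 0.00223) and collagen genes (0.26, adjusted p = 0.0189) had positive medians. With an estimated correlation these 8 lists had adjusted p of 0.488 to 0.839. All 15 skeletal muscle genes were positive, with a median of 2.09 (adjusted p = 3.59e-16, and 0.488 with an estimated correlation). That list scored 0.89, 5.74, 4.27 and 1.31 in the 4 A91-DsEV libraries and 1.32, 0.98 and 0.96 in the PBS libraries.

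Without both muscle-rich libraries, A91-DsEV replicates 2 and 3, 11 of the 13 list calls ended (adjusted p of 0.061 to 0.925), leaving the meningeal and collagen lists among them, and the lipid-handling phagocyte list had a mean of -0.01. The T cell call ended too, although every A91-DsEV library scored lower (1.92 to 2.01) than every PBS library (2.12 to 2.46). Its loss therefore does not show that the T cell difference lay in the muscle-rich libraries. Leaving out 1 library ended 1 call without A91-DsEV replicate 1 (collagen, 0.285), 6 without replicate 2 (0.113 to 0.667), 3 without replicate 3 (0.136 to 0.358), 2 without replicate 4 (0.0981 to 0.274), and 4, 5 and 3 without PBS replicates 1, 2 and 3 (0.0759 to 0.366, 0.191 to 0.998 and 0.107 to 0.912). The skeletal muscle, lipid-handling phagocyte, cholesterol and MHC class I calls held in each of these 7 fits, with means that shrank from 1.97 to 1.22 for muscle without A91-DsEV replicate 2, from -0.27 to -0.17 and -0.12 for lipid-handling phagocytes without A91-DsEV replicate 2 and PBS replicate 2, and from -0.15 to -0.09 for MHC class I without A91-DsEV replicate 2 or PBS replicate 1. With pancreatic traces as a term, the peripheral nerve, complement and astrocyte calls ended (0.0564 to 0.619), and among only the libraries without traces, 2 of A91-DsEV and 3 of PBS, 5 calls ended (0.108 to 0.849).

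Lists for T cells, MHC class II presentation, neurotrophic factors and alternative macrophage activation did not pass at time points 3 and 7. T cell genes had medians of -0.07 (adjusted p = 0.246) and 0.02 (adjusted p = 0.0957), and MHC class II genes medians of 0.21 (adjusted p = 0.086) and -0.05. The 15 neurotrophic factor genes had medians of 0.01 (adjusted p = 0.648) and -0.19 (adjusted p = 0.0813), and genes of alternative macrophage activation medians of -0.01 (adjusted p = 0.521) and -0.15 (adjusted p = 0.414). The MHC class II, neurotrophic and alternative activation lists did not pass at time point 14 either. PBS replicate 3 of time point 3 stood apart, with a T cell score of 2.22 against 1.41 and 1.32 in PBS replicates 1 and 2. Its MHC class II score was 3.96 against 2.79 and 3.23. The absence of these calls at time point 3 therefore does not show equal levels.

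Averaged over the 3 time points, H2bc6 lay 0.34 ± 0.08 higher in A91-DsEV on the log2 scale, and Plin4 -0.80 ± 0.21, the cold-induced Rbm3 -0.42 ± 0.10, Nudt22 -0.29 ± 0.07 and Zfp28 -0.23 ± 0.05 lower. No gene passed (smallest adjusted p = 1.0 in limma), and 524 had an unadjusted p below 0.05, where 698 were expected. The difference of the treatment effect between time points had its smallest p for Dbp, with log2 fold changes of 0.47, -1.17 and 0.12 at time points 3, 7 and 14, and for Capsl, with 0.81, -0.03 and -0.21. No gene passed this interaction test (smallest adjusted p = 0.749 in limma), and 722 had an unadjusted p below 0.05. In the averaged comparison 12 lists passed the preset camera test, 9 higher and 3 lower, among them skeletal muscle (0.96), red blood cells (0.52), cell cycle (0.12), homeostatic microglia (0.11), reactive astrocytes (-0.14) and axon regeneration (-0.13, 18 of 19 negative), and 0 passed with an estimated correlation (adjusted p of at least 0.531). Single libraries stood apart in these lists: the muscle scores were 5.74 and 4.27 in A91-DsEV replicates 2 and 3 of time point 14, the red blood cell score was 9.24 in A91-DsEV replicate 1 of time point 7, and PBS replicate 1 of time point 3 had a cell cycle score of 3.03 and a microglial score of 4.13. Without PBS replicate 2 of time point 3, 2 genes passed the averaged test, Fbxw23 (-0.47) and Serpina3m (-0.93), and 3 passed the interaction test.

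Between time points 3 and 7 in PBS, genes of phagocytes that take up lipid rose and genes of cholesterol biosynthesis fell. Apoe rose from 1270 ± 53.3 to 7069 ± 1495 FPKM (SD, n = 3 and 3), a log2 fold change of 2.46 ± 0.17 (SE, adjusted p = 3.4e-07), and Gpnmb from 83.4 ± 22.3 to 1120 ± 315 FPKM. Trem2, a lipid-sensing receptor of phagocytes, rose from 67.3 ± 8.48 to 270 ± 72.4 FPKM. Of 20 lipid-handling phagocyte genes, 17 rose, and 18 rose when adjusted over the list alone. Of 18 cholesterol genes, 17 fell, with the same number adjusted over the list alone, Msmo1, a sterol oxidase, from 63.0 ± 7.10 to 23.1 ± 2.61 FPKM.

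Scar, complement and antigen presentation genes rose in the same interval. Of 20 collagen and scar genes, 17 rose, Col1a1 from 46.8 ± 34.9 to 374 ± 121 FPKM. Of 13 complement genes, 8 rose, C1qa from 410 ± 13.6 to 974 ± 126 FPKM. Of 12 MHC class I genes, 8 rose (10 adjusted over the list alone), with B2m from 624 ± 66.8 to 1171 ± 109 FPKM, and 6 of 14 MHC class II genes rose, with the protease Ctss from 463 ± 30.3 to 1318 ± 217 FPKM. Among 18 macrophage genes 10 rose and 2 fell, and 5 of 11 homeostatic microglia genes rose. Of 18 oxidative phosphorylation genes, 15 fell (18 adjusted over the list alone), and of 19 neuronal genes 7 fell (17 adjusted over the list alone), with the synaptic protein Snap25 from 556 ± 234 to 218 ± 41.6 FPKM. PBS replicate 1 of time point 3 stood apart in both lists. Its neuronal score was 5.70 against 5.01 and 5.19 in the other replicates, and 4.27 to 4.64 at time point 7. For oxidative phosphorylation it was 7.68 against 7.29 in both other replicates, and 6.86 to 6.96 at time point 7. The largest rises by the naming rule were those of the proteases Mmp13 (3.92 ± 0.88) and Mmp12 (3.72 ± 0.41), and the largest falls those of Serpina3m (-2.77 ± 0.39), the acute-phase protein Lcn2 (-2.52 ± 0.49), Arl4d (-2.37 ± 0.43), Plin4 (-2.23 ± 0.39) and the heat shock protein Hspb1 (-2.18 ± 0.33).

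In all, 1671 genes rose and 2023 fell between time points 3 and 7 in PBS (limma, adjusted p below 0.05), of which 404 and 157 changed at least 2-fold. The groups did not overlap in 6304 genes (45.1%), against 10% by chance. The preset camera test was passed by 17 lists and 0 passed with an estimated correlation (smallest adjusted p = 0.452), while fry, which asks whether a list moves one way, was passed by 16. Rescaled to equal FPKM totals the split was 1486 risen and 1178 fallen, and the count of called genes fell to 1823 without PBS replicate 1 of time point 7 and to 1852 without PBS replicate 1 of time point 3.

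Between time points 7 and 14 in PBS, genes of dividing cells fell together, and part of the genes of alternatively activated macrophages fell. All 24 cell cycle genes fell, also when adjusted over the list alone, with a median log2 fold change of -2.05. Cyclin B2, Ccnb2, fell from 15.6 ± 3.06 to 1.84 ± 0.318 FPKM (SD, n = 3 and 3), a log2 fold change of -2.53 ± 0.20 (SE, adjusted p = 1.2e-06). Arg1, arginase of alternatively activated macrophages, fell from 122 ± 25.5 to 2.96 ± 1.46 FPKM. Spp1, the phagocyte product osteopontin, fell from 9645 ± 2116 to 989 ± 197 FPKM, and Hmox1, a haem-degrading enzyme, from 476 ± 118 to 50.8 ± 10.3 FPKM.

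Of 12 alternative activation genes, 7 fell (10 adjusted over the list alone), and of 20 collagen and scar genes 10 fell (12 over the list alone), Fn1 from 281 ± 36.9 to 83.9 ± 33.7 FPKM. Among 20 lipid-handling phagocyte genes 9 fell and 1 rose. Of 19 neuronal genes, 3 rose (18 adjusted over the list alone), the neurofilament Nefh from 76.9 ± 6.30 to 179 ± 18.0 FPKM, and 4 of 16 oligodendrocyte genes rose, Opalin from 14.1 ± 1.45 to 35.4 ± 6.26 FPKM. Lcn2 (2.35 ± 0.49), the prostaglandin synthase Ptgds (1.91 ± 0.39), the T cell and NK cell chemokine Ccl5 (1.81 ± 0.26), Ms4a4b (1.56 ± 0.30) and Clec3b (1.54 ± 0.33) had the largest rises by the naming rule. In all, 581 genes rose and 1031 fell, of which 68 and 275 changed at least 2-fold. The groups did not overlap in 5914 genes (42.4%), against 10% by chance. The preset camera test was passed by 14 lists, 0 passed with an estimated correlation (smallest adjusted p = 0.189), and 3 passed fry.

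The number of called genes between time points 7 and 14 in PBS was 460, 502, 491 and 474 without PBS replicate 3 or 1 of time point 7 and replicate 1 or 3 of time point 14, 1004 after rescaling to equal totals, 3394 when only these 2 groups were fitted and 6625 with array weights. Without the library rich in pancreatic transcripts, which enters the shared estimate of the spread, 1776 genes rose and 1370 fell, and with values rescaled without the pancreatic genes 1040 rose and 971 fell.

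Between time points 3 and 7 in A91-DsEV, lipid-handling phagocyte genes rose and cholesterol genes fell, as in PBS, and genes of myelin and endothelium fell. Apoe rose from 1486 ± 51.0 to 7528 ± 1225 FPKM (SD, n = 4 and 4), a log2 fold change of 2.33 ± 0.15 (SE, adjusted p = 7.35e-08), and 18 of 20 lipid-handling phagocyte genes rose. All 18 cholesterol genes fell, Sqle, the squalene epoxidase, from 33.4 ± 2.54 to 12.2 ± 2.66 FPKM. Both numbers were the same when adjusted over the list alone. Of 16 oligodendrocyte genes, 10 fell (12 adjusted over the list alone), Mag from 288 ± 14.4 to 163 ± 31.7 FPKM, and of 16 endothelial genes 11 fell, Pecam1 from 42.8 ± 12.3 to 19.6 ± 2.25 FPKM. The myelin list scored 6.10 in replicate 2 of time point 7, the library rich in pancreatic transcripts, 6.35 to 6.95 in the other 3 libraries of that group and 7.15 to 7.26 at time point 3. In PBS the mean scores were lower at time point 7 as well. The myelin score went from 6.9 to 6.64 in PBS and from 7.19 to 6.55 in A91-DsEV. The endothelial score went from 4.49 to 4.11 in PBS and from 4.51 to 3.91 in A91-DsEV. PBS replicate 1 of time point 3 had a myelin score of 6.57, against 7.24 and 6.91 in PBS replicates 2 and 3.

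Of 20 collagen and scar genes, 12 rose (15 adjusted over the list alone), Postn, a matrix protein, from 8.75 ± 3.83 to 81.7 ± 33.6 FPKM. Of 12 MHC class I genes, 6 rose, and of 7 T cell genes 2 rose, the costimulatory receptor Cd28 from 0.437 ± 0.163 to 3.38 ± 1.13 FPKM and Cd4 with a log2 fold change of 0.46 ± 0.15. Tgm1, a transglutaminase (-2.56 ± 0.28), Prg4 (-1.89 ± 0.50), Uts2 (-1.88 ± 0.36), Gpd1 (-1.72 ± 0.16) and Apold1 (-1.68 ± 0.37) had the largest falls by the naming rule. In all, 911 genes rose and 2219 fell, of which 185 and 66 changed at least 2-fold, and 3255 genes did not overlap (23.3%, against 2.9% by chance). The preset camera test was passed by 17 lists, 0 passed with an estimated correlation (smallest adjusted p = 0.245), and 12 passed fry. The median log2 fold change of all genes was -0.126, and quantile normalization moved it to -0.035 with 1331 genes risen and 1228 fallen. The count of called genes was 1857 without the library rich in pancreatic transcripts (replicate 2 of time point 7), 2015 without replicate 3 of time point 7, 2079 without replicate 1 of time point 3 and 1739 when only these 2 groups were fitted.

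Between time points 7 and 14 in A91-DsEV, cell cycle genes fell and neuronal and synaptic genes rose. All 24 cell cycle genes fell, Ccnb1 from 13.4 ± 5.04 to 1.63 ± 0.635 FPKM (SD, n = 4 and 4), a log2 fold change of -2.41 ± 0.21 (SE, adjusted p = 1.06e-06). Of 19 neuronal genes, 18 rose (19 adjusted over the list alone), Chat, the enzyme that makes acetylcholine in motor neurons, from 2.25 ± 1.68 to 5.83 ± 1.02 FPKM, and all 18 synaptic genes rose, the glutamate receptor subunit Gria1 from 9.58 ± 3.64 to 17.8 ± 1.56 FPKM. The neuronal list scored 3.43 in replicate 2 of time point 7, the library rich in pancreatic transcripts, and 4.33 to 5.07 in the other 3 libraries of that group. The mean neuronal score rose alike, from 4.48 to 5.39 in PBS and from 4.47 to 5.49 in A91-DsEV. The mean synaptic score went from 2.4 to 3.07 in PBS and from 2.35 to 3.16 in A91-DsEV. The larger count of called genes in A91-DsEV therefore does not show a larger rise than in PBS.

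Of 18 cholesterol genes, 15 rose (17 adjusted over the list alone), and of 16 oligodendrocyte genes 12 rose, Mag from 163 ± 31.7 to 241 ± 11.5 FPKM. Of 14 peripheral nerve genes, 7 rose, and 6 of 12 astrocyte genes rose. Of 20 lipid-handling phagocyte genes, 15 fell (16 over the list alone), the fatty acid receptor Cd36 with a log2 fold change of -2.86 ± 0.34, and 8 of 12 alternative activation genes fell, Arg1 with a log2 fold change of -4.13 ± 0.58. The neuropeptide genes Calca (2.80 ± 0.38) and Uts2 (2.71 ± 0.36) had the largest rises by the naming rule, followed by Mmp3 (2.68 ± 0.75), Ptgds (2.55 ± 0.34) and Myoc (2.32 ± 0.28). In all, 3251 genes rose and 1715 fell, of which 196 and 246 changed at least 2-fold, and 3961 genes did not overlap (28.4%, against 2.9% by chance). The preset camera test was passed by 13 lists, 0 passed with an estimated correlation (smallest adjusted p = 0.274), and 16 passed fry.

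The split of the A91-DsEV change between time points 7 and 14 was 2626 risen and 2320 fallen after quantile normalization, 4379 and 1052 after rescaling to equal FPKM totals, and 1284 and 1033 without the library rich in pancreatic transcripts. The median log2 fold change of all genes was 0.083, and 0.009 and 0.202 with the scalings named first. Without replicate 2 of time point 14, 2554 genes passed, without replicate 3 of time point 7, 2938, and when only these 2 groups were fitted, 1808.

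The time courses of both treatments were compared across genes, which are not independent replicates, and shared no library. They came from the same fit, with a shared spread for each gene. A gene of small spread could pass more easily in both, so the numbers for independent lists below may be too low. Between time points 3 and 7 the log2 fold changes had a Pearson r of 0.75 and a Spearman rho of 0.72 across genes. In both treatments 1736 genes passed, and 1735 of them moved in the same direction, 793 up and 942 down, where independent lists would share 109 and 321. Between time points 7 and 14, r was 0.84 and rho 0.86, and all 1373 genes that passed in both treatments moved in the same direction, 490 up and 883 down, where independent lists would share 135 and 127. Gpnmb rose between time points 3 and 7 by 3.72 ± 0.31 in PBS and 3.30 ± 0.26 in A91-DsEV on the log2 scale, and Spp1 changed between time points 7 and 14 by -3.28 ± 0.31 and -3.14 ± 0.27. The slope of the A91-DsEV on the PBS fold changes across genes was 0.62 between time points 3 and 7 and 0.92 between 7 and 14.

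**Figure D3:**
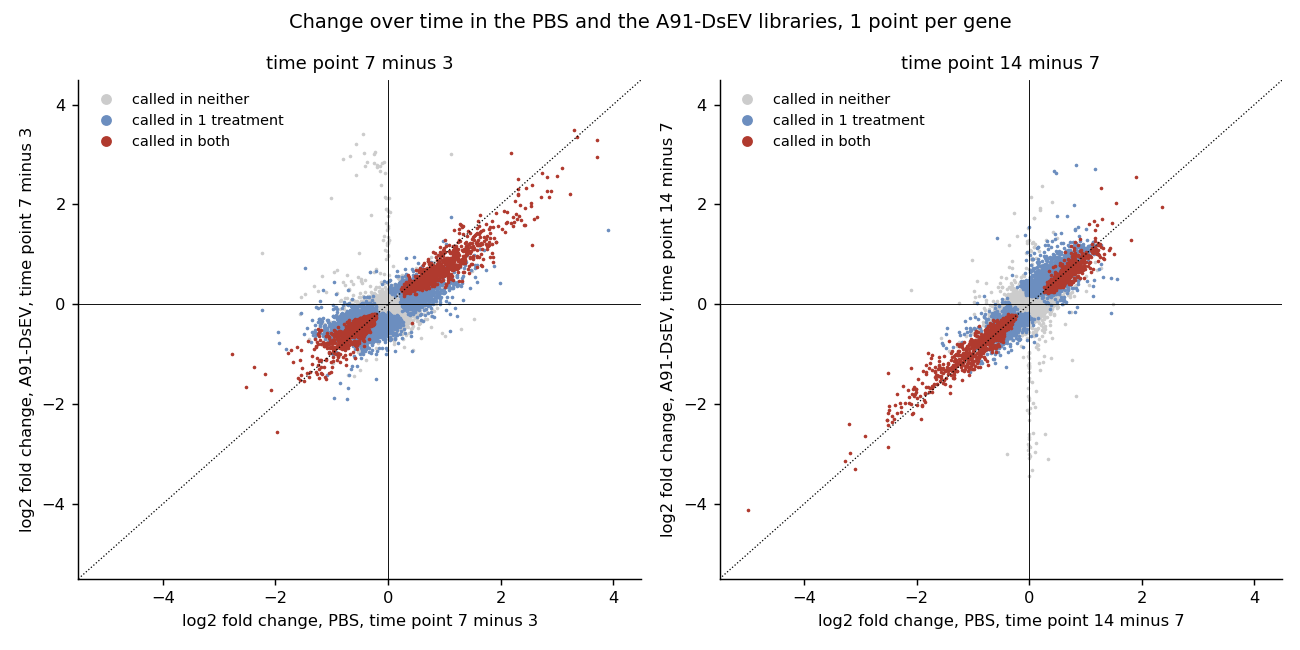
Log2 fold change of each gene between successive time points in PBS (x axes) and in A91-DsEV (y axes), between time points 3 and 7 on the left and 7 and 14 on the right. Grey points passed in neither treatment, blue in 1 and red in both. The red points, 1736 and 1373 genes, lie in the quadrants of equal sign apart from 1 gene, and a grey group near 0 on the x axes holds pancreatic genes of A91-DsEV replicate 2 of time point 7.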

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

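The tests of muscle, pancreas and shared reads in this part were chosen after the result was seen. In groups of 4 libraries, a value was singled out when its gap to the nearest other library was above Dixon's critical share of the whole range, which happens by chance in about 1 in 20 groups. This held in 18 of 867 tests, 2 of 114 for list scores and 15 of 735 for named genes.

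A91-DsEV replicate 4 of time point 3 stood apart in the neutrophil list (gap share 0.876, score 5.46), the cartilage and bone list (0.938, score 2.56), Col10a1 (0.988), the antibody joining chain Jchain (0.967) and the fast muscle myosin Myh2 (0.888). In that library the granule genes Ngp and Camp measured 374 and 138 FPKM, where the next highest libraries had 36.0 and 15.4 FPKM. In the same group, Cox5a was apart in replicate 2 (0.859), and Mmp12 (0.848) in replicate 3. At time point 7, C1s1 (0.941) and the relative depth (0.863) were apart in replicate 3, the death receptor Tnfrsf10b (0.937) in replicate 2 and Ccnb2 (0.834, low) in replicate 4. At time point 14, H2-T23 (0.919, low), Hmgcs1 (0.83) and Myoc (0.836) were apart in replicate 2, Col10a1 (0.891) in replicate 3 and Ccnb1 (0.879) in replicate 4.

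The treatment effect on several lists differed between time points by the preset camera test of the interaction. From time point 3 to 7 the median log2 difference was -0.50 for cell cycle genes, -0.42 for homeostatic microglia, -0.56 for ependymal and cilia genes, -0.39 for complement, -0.44 for immediate-early genes and -0.38 for oligodendrocytes, and 0.21 for oxidative phosphorylation and 0.35 for neurons. None of these passed with an estimated correlation (adjusted p of at least 0.822). From time point 7 to 14 it was 0.36 for cholesterol biosynthesis, 0.62 for meninges, 0.29 for immediate-early genes, 0.46 for collagens and 1.59 for skeletal muscle, and -0.24 for lipid-handling phagocytes, -0.12 for MHC class I, -0.54 for red blood cells, -0.31 for T cells and -0.15 for B cells. None of these passed with an estimated correlation either (adjusted p of at least 0.667). Libraries that stood apart enter these differences. PBS replicate 1 of time point 3 had a cell cycle score of 3.03, a microglial score of 4.13 and a neuronal score of 5.70. A91-DsEV replicates 2 and 3 of time point 14 had muscle scores of 5.74 and 4.27.

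Transcripts of other tissues in single libraries were weighed as a pattern. At time point 14, 2 of the 4 A91-DsEV libraries had skeletal muscle scores more than 2 above the highest PBS library (1.32), a bound written from these scores, so it does not decide whether muscle was carried into them. Pancreas tissue or its RNA in A91-DsEV replicate 2 of time point 7 fits the values: all 8 endocrine pancreas genes and acinar factors lay above every other library there, Ins2 at 71.9 FPKM against at most 0.0479 FPKM, beside the 13.1% of FPKM in exocrine genes. Across the 20 exocrine genes, the mean excess of the 8 libraries with traces over those without followed the levels of that library. The Spearman rho was 0.95 across genes, which are not independent replicates. Reads of that library counted in libraries handled beside it are a candidate source. Another pancreatic source could give the same order of genes, so the rho does not tell them apart. How the transcripts got there stays open, and no biological explanation was tested. Traces and treatment of time point 7 cannot be told apart, since all 4 A91-DsEV and 0 of 3 PBS libraries held pancreatic transcripts.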

How the results depend on the processing

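The alternatives on pancreatic transcripts, on both muscle-rich libraries and with array weights were chosen after the data were seen, and the cause of a change was not tested unless it is named. Of 362 named gene results, 360 kept their direction under every alternative, and of the 247 past the threshold 178 stayed past it in every alternative chosen before the data were examined. These genes were named for their change or p in the main fit, and the alternatives share its libraries. A kept direction was therefore largely fixed beforehand and is not separate evidence. All 247 belong to the time courses, since no gene passed between the treatments.

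For A91-DsEV against PBS at time point 3, 0 genes passed, 16 at an unadjusted p below 0.05 with a 2-fold change, 1 without a filter on low values, 3 with pancreatic traces as a term, 3 with values rescaled without exocrine genes, 1 without A91-DsEV_7 replicate 2 in the whole fit, 6 among libraries without traces and 2 with array weights. The libraries without traces also leave out PBS_3 replicate 2. At time point 7, 15 genes passed at the unadjusted p with a 2-fold change, and at time point 14, 20 did, and 1 without a filter. The interaction had 37 at that unadjusted threshold. With the correlation estimated per list, 0 lists passed at each time point.

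Leaving out 1 library gave 0 to 103 genes and 5 to 14 lists at time point 3, 0 genes and 7 to 17 lists at time point 7, 0 genes and 10 to 17 lists at time point 14, 0 to 2 genes for the average and 0 to 3 for the interaction. The highest gene counts came without PBS_3 replicate 2. In the time courses it gave 1823 to 3719 genes (PBS, 3 to 7), 460 to 1686 (PBS, 7 to 14), 1857 to 3920 (A91-DsEV, 3 to 7) and 2317 to 5973 (A91-DsEV, 7 to 14).

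At the unadjusted p with a 2-fold change the time courses had 574, 398, 259 and 459 genes in that order, fewer because of the fold. With only the groups compared, PBS from 7 to 14 had 3394 genes, and A91-DsEV had 1739 and 1808. PBS from 7 to 14 had 1004 genes rescaled to equal totals, 6625 with array weights and 3146 without A91-DsEV_7 replicate 2.

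The values showed no sign that equal replicate numbers paired the libraries: 1 of 9 pairs of equal number had a correlation above 0.1, and 2 of 9 PBS libraries matched best with their own number. These correlations cannot exclude a pairing, and the labels do not say whether the numbers pair libraries. With the replicate block, 1 gene passed at time point 3 (Plin4, -1.88), 1 at time point 7 (Dbp, -1.35), and 778 in PBS from 7 to 14.

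Some directions reversed. Xbp1 at time point 7 was -0.05 without A91-DsEV_7 replicate 2 and up to 0.21 without replicate 4. With traces as a term at time point 7, list means were -0.09 (meninges), -0.06 (reactive astrocytes) and 0.04 (peripheral nerve), which turned relative to other genes. That term was set by libraries of time points 3 and 14, so these turns do not test the difference at time point 7. At time point 14 without both muscle-rich libraries, 5 lists passed, and means were 0.06 (complement), 0.03 (cytokines), -0.01 (lipid-handling phagocytes), 0.06 (macrophages), -0.01 (reactive astrocytes) and 0 (peripheral nerve). Complement ranged from -0.30 without PBS_14 replicate 3 to 0.03 without PBS_14 replicate 2. Peripheral nerve was 0.06 with traces as a term and 0.06 among libraries without traces, where Ngfr was 0.05.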

Other observations

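The counts of splits in this part were chosen after the results were seen, as were the fits of gene sets without a library. For the other tests of gene sets and of single libraries, predictions were written before those tests were run. They followed from patterns already seen in the main results, so they were not fixed before the data were examined. The rule for excluding a single library as the cause was added after the values were seen. Of 12 genes of pericytes and smooth muscle, 6 rose between time points 3 and 7 in PBS, with a median of 0.50, and 3 rose and 1 fell in A91-DsEV, with a median of 0.34. Between time points 7 and 14, 1 of them rose and 4 fell in each treatment, with medians of -0.53 in PBS and -0.25 in A91-DsEV. With an estimated correlation this list had adjusted p of 0.469 to 0.696 in the 4 intervals. Of 19 apoptosis and cell death genes, 7 fell in PBS and 8 in A91-DsEV between time points 7 and 14, and of 19 glycolysis and hypoxia genes 10 fell in each treatment between time points 3 and 7. Dbp averaged 9.86, 22.4 and 31.9 FPKM in PBS at time points 3, 7 and 14, and 14.7, 9.68 and 34.5 FPKM in A91-DsEV.

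Single libraries held further transcripts of their own. PBS replicate 3 of time point 3 had the muscle precursor factors Myod1 and Myog at 4.74 and 8.83 FPKM, against at most 0.477 and 1.54 FPKM in any other library. PBS replicate 2 of time point 7 had the sensory neuron genes Scn10a and Pirt at 2.53 and 4.94 FPKM, against at most 0.0322 and 0.192 FPKM elsewhere. The sensory neuron genes Calca and Prph were not highest in that library. Haemoglobin Hbb-bs was the most abundant gene in several libraries, at up to 6.8% of the FPKM in A91-DsEV replicate 1 of time point 7 and 6.18% in A91-DsEV replicate 1 of time point 14.

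Lower Plin4, Fkbp5, Pla2g3 and Otud1 at time point 3 led to the hypothesis of weaker glucocorticoid action in the A91-DsEV animals or at their collection. The highest median of the 4 genes over the 3 fits without a PBS library was -0.84, against -1.21 with all libraries, but these genes were picked because they were lower, so this does not exclude that one PBS library stood apart. The other 18 glucocorticoid-induced genes were all lower, with a mean log2 difference of -0.50 (exact two-sided permutation p = 0.086, adjusted p = 0.387 over 9 tests of 3 gene sets), but the mean was -0.16 without PBS replicate 1, with 12 of 17 genes lower, and -0.76 and -0.59 without PBS replicates 2 and 3. Less glucocorticoid action in A91-DsEV may contribute, and it cannot be told apart from PBS replicate 1 standing apart with these libraries.

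Lower Dbp, Per2 and Per3 at time point 7 led to the hypothesis that tissue of the groups was collected at another hour of the day. The highest median of the 3 genes over the 7 fits without a library was -0.63, against -0.78 with all, but these genes too were picked because they were lower. The other 8 clock outputs were all lower, with a mean of -0.34 (exact two-sided permutation p = 0.2, adjusted 0.515) that ranged from -0.47 to -0.21 without a library, and the opposite-phase genes had a mean of 0.20 (exact two-sided permutation p = 0.057, adjusted 0.387, where the smallest possible p is 0.029). The opposite-phase genes were Npas2 (0.48), Arntl (0.28), Nfil3 (0.10) and Clock (-0.05). Npas2 was already named above as higher in these same libraries, so that mean is not independent support. The hour of collection may differ, but these values decide neither that nor whether one library stood apart, no source used here gives that hour, and an effect of the treatment on the clock stays open.

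Chance was not excluded for the genes at an unadjusted p below 0.05 in any comparison of A91-DsEV with PBS, or for the lists at time points 3, 7 and 14, while lists of the average and the interaction were not tested with splits. At time point 3, 5 of the 35 splits of the libraries gave as many such genes as the real one (1370, highest other 2119) and 31 of 35 as many lists (10, highest other 19, median 14). The splits of time point 7 were 16 of 35 for genes (544, highest other 3943) and 23 of 35 for lists (13, highest other 21, median 14), and those of time point 14 were 17 of 35 (275, highest other 1273) and 18 of 35 (13, highest other 22, median 12). For the average, 46 of 100 drawn splits gave as many genes (524, highest other 3037), and for the interaction 26 of 100 (722, highest other 2611). Splits of the genes that passed after adjustment test nothing here, since the real count was 0 in each of these comparisons and every split must reach it: 35 of 35 at time points 3, 7 and 14 (highest other 2, 928 and 0), and 100 of 100 for the average and the interaction (highest other 1 in both).

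One split of time point 7 that set A91-DsEV replicates 1 and 4 with PBS replicates 2 and 3 against the others called 928 genes, and one with A91-DsEV replicates 2 and 3 and PBS replicates 1 and 3 called 737. They are the largest of the 35 and nearly the same division, apart from PBS replicate 3, and point to a structure of the samples other than the treatment, which was not tested itself. For the A91-DsEV time courses, 1 of 35 splits, the real one, gave as many genes between time points 3 and 7 (3130, highest other 180) and 1 of 35 between time points 7 and 14 (4966, highest other 3077). This is the smallest share that 35 splits can give, and it was not adjusted over both intervals. For PBS the 10 splits are too few for a share under 0.05 (3694 genes, highest other 0, and 1612 genes, highest other 0).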
